A study of Mus musculus with 80 samples.

How the data were processed

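The series holds CUT&RUN libraries for H3K27me3 and their inputs from purified mouse uterine fibroblasts. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.7.5c, handled with samtools 1.10, Picard, bedtools 2.29.1 and bedGraphToBigWig 2.8, and broad peaks were called with macs2 2.2.7.1. The deposited broad peak lists give for each peak its position, the fold over background, and -log10 p and -log10 q, as made by MACS2 per the labels. Each list pools the 3 samples of a group, so 16 lists stand for 48 of the 80 samples. The other 32 samples, 20 of them inputs, enter no list and are not analysed here. One library of Pgr-Cre cKO GD14.5 IS is titled as an input while its antibody field names H3K27me3, and was placed with the inputs.

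The peak lists are lenient. In the Kdm6b set the smallest -log10 p was 0.340 to 0.349 and the median fold 1.12 to 1.15, and in the B6CBAF1/J set 0.330 to 0.336 and 1.09. The median -log10 p was 0.611 to 0.667 in the Kdm6b set and 0.577 to 0.596 in the B6CBAF1/J set. Peaks of the first set lie at least 405 bp apart and those of the second 605 bp, so lists of the 2 sets were not compared with each other. Read depth is not given in the sources used here, so precision comes only from the spread over pairs of lists. The Pgr-Cre GD14.5 IS lists carry the name of a separate round of peak calling.

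Coverage was computed for 21627 protein-coding genes, 966 on the X, as the percent of the gene span with 2 kb on either side that lies inside peaks. The plan was a window around the transcription start. The annotation used has no strand, so the whole span was taken, and a window at the gene end with the higher coverage was added as an alternative. Positions were turned into 1-based mm10 coordinates. Analyses used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

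The 14 comparisons, the tests, the size rule, the rule for named genes, the 18 gene lists and the first set of alternatives were fixed before the data were examined. For cKO against control, the 5 Pgr-Cre pairs and the 1 Pdgfra-Cre pair were taken as 6 pairs of independent lists. This independence is assumed, since sample titles do not say whether Pgr-Cre GD14.5 IS and IIS fibroblasts came from the same females. Covered length and list means were tested with an exact two-sided sign-flip permutation test over 64 flips, whose smallest p is 0.03125. Genes with a mean coverage of at least 5% were tested with limma on the 6 paired differences, with Benjamini-Hochberg adjusted p under 0.05. A rise or fall over the 6 pairs means that a gene passed this test. Counts adjusted over the list alone repeat the adjustment within 1 list.

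Single comparisons have 1 list per side and no test. A gene counted as gained or lost at a difference of at least 50 points, with exact 95% binomial intervals on the share gained. List means were placed among 10000 random lists matched on mean coverage. Named genes were the 10 largest gains and the 10 largest losses that kept at least 50 points at equal covered length, the 10 genes each way with the smallest p over the 6 pairs among those with the same sign in all 6, Kdm6b, Pgr and Pdgfra, and the 4 members of each list with the largest change.

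For equal covered length, peaks were taken from the lowest p upward until each list reached 80% of the shortest list of its set, 487 Mb for the Kdm6b set and 544 Mb for B6CBAF1/J. Other alternatives were peaks with -log10 q of at least 2, peaks with a fold of at least 3, flanks of 5 kb, changes of 25 points, no filter on mean coverage, unpaired fits, subtraction of the median difference, and leaving out each pair. Alternatives added after the data were seen were the gene-end window, autosomes alone, limma with a trend and robust prior, the rotation test, and those for the X chromosome and the gene families. The limma procedure was tested on simulated data, with shifts of 10, 20 and 40 points added to known genes, and recovered 22.7%, 55.2% and 85.1% of them, with 7.63% of calls false.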

Results

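H3K27me3, the Polycomb mark of trimethylated lysine 27 on histone H3, was profiled by CUT&RUN, in which an antibody directs a nuclease to the marked chromatin, in fibroblasts purified from the mouse uterus. Kdm6b, which encodes an H3K27 demethylase, was deleted with Pgr-Cre, active in cells that express the progesterone receptor, or with Pdgfra-Cre, active in fibroblasts. These conditional knockouts are called cKO here and were set against Kdm6b f/f controls. Pgr-Cre cKO and control fibroblasts came from the tissue between implantation sites (IIS) on gestation days GD5.5, GD8.5 and GD14.5 and from implantation sites (IS) on GD14.5 and GD18.5, and the Pdgfra-Cre pair came from GD14.5 IS. A further set of B6CBAF1/J females covered GD0.5 uterus, GD5.5 IIS after natural mating, GD5.5 uterus after a vasectomized mating, and non-pregnant females given progesterone for 3 days. The labels name 80 samples, of which 48 enter the 16 peak lists compared here, 3 samples per group and 1 list per group.

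Each of the 12 lists of the Kdm6b set held 221350 to 287629 peaks covering 609 to 740 Mb of the genome, and each of the 4 B6CBAF1/J lists held 131900 to 167542 peaks covering 681 to 704 Mb. The samples of a group were pooled before the peaks were called, so a list has no replicate values, and the number of reads behind each list is unknown. Gene values below are coverage, the percent of a gene span with 2 kb on either side that lies inside peaks, in the mm10 build with positions counted from 1. Differences are in percentage points, cKO minus control unless stated. Intervals on shares of genes cover the counting of genes only. Of the peaks in cKO lists, 60.6% (Pdgfra-Cre GD14.5 IS) to 71.3% (GD14.5 IIS) overlapped a peak of their control list by at least 1 bp.

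The first question was how loss of the demethylase altered the extent of H3K27me3. Less of the X chromosome lay inside H3K27me3 peaks in the cKO list than in the control list of every pair. This length lay almost wholly in weak peaks, with at most 0.0605 Mb of X at a -log10 q of at least 2 in any of the 12 lists. Counting only peaks at a fold of at least 3, at most 0.00732 Mb per list, the X was higher in cKO in all 6 pairs. In Pgr-Cre fibroblasts of GD14.5 IS, peaks covered 52.4 Mb of the X in cKO against 90.1 Mb in control, and in the Pdgfra-Cre pair 73.9 Mb against 89.1 Mb. At GD18.5 the values were 77.3 Mb against 87.4 Mb. Of 817 X-linked genes tested with limma, 226 fell and 1 rose. Among them Rbbp7, a histone-binding subunit of Polycomb complexes, fell from 64.1% to 41.3% (difference -22.8 ± 13.3, SD, 6 pairs, adjusted p = 0.0248), though with the gene-end window it did not pass (-30.2, adjusted p = 0.0912).

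The log2 ratio of X covered length averaged -0.35 ± 0.23 (SD, n = 6 pairs, lower in 6 of 6). The exact two-sided sign-flip permutation test gave p = 0.03125, the smallest value that 6 pairs allow. With all lists of the set brought to the same covered length the mean log2 ratio was -0.65, again lower in 6 of 6 pairs. The X was singled out after the values of all chromosomes were seen. The autosomes went the other way, with a mean log2 ratio of 0.12 ± 0.13 (higher in 5 of 6 pairs, exact sign-flip permutation p = 0.0625), and covered length over all chromosomes averaged 0.06 ± 0.12 (higher in 5 of 6, exact p = 0.25). Neither passed the test. At equal covered length the autosomal mean was 0.06 and higher in 6 of 6 pairs (exact p = 0.03125), which mirrors the X because the total is fixed. Counting only peaks with a -log10 q of at least 2, the covered length was lower in cKO in 5 of 6 pairs, with a mean log2 ratio of -1.91 (exact sign-flip permutation p = 0.0625), with 0.495 Mb against 14.8 Mb in Pgr-Cre GD14.5 IS. Pgr-Cre GD14.5 IIS was the exception, with 7.43 Mb in cKO and 5.24 Mb in control.

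**Figure D1:**
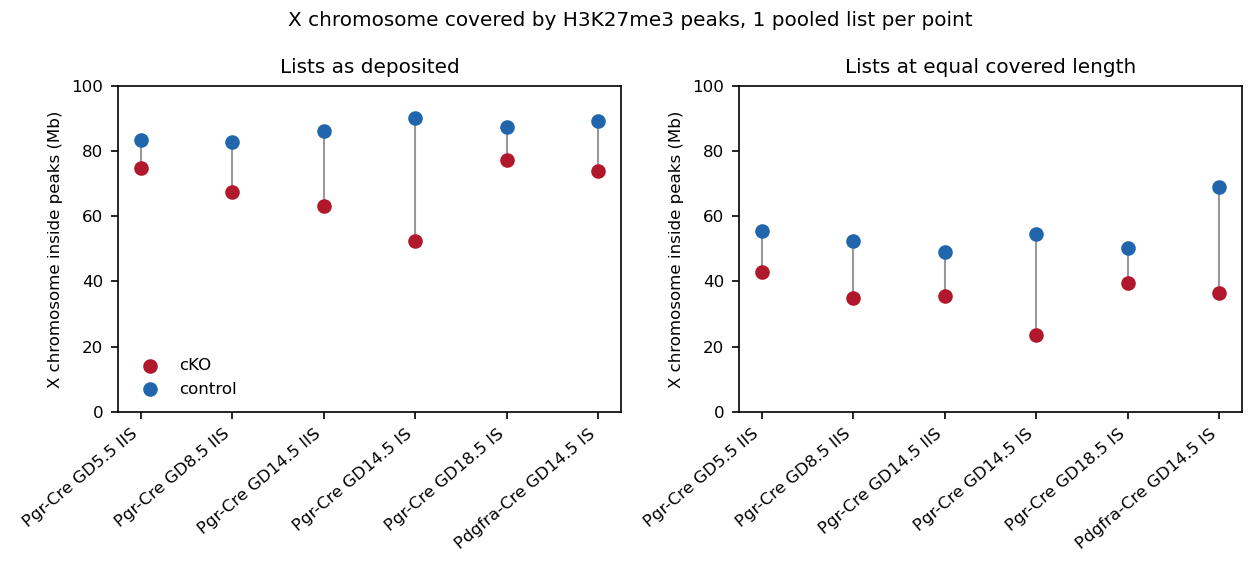
Length of the X chromosome inside H3K27me3 peaks (Mb, vertical axis) in the cKO list and the control list of each of 6 pairs (horizontal axis), for the lists as deposited and at equal covered length. Each point is 1 pooled list, and cKO lies below control in 6 of 6 pairs in both panels.

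Across the 6 pairs, some genes of the contraction and parturition list had more of their span inside H3K27me3 peaks in cKO lists. Slco2a1, the prostaglandin transporter (chromosome 9, 103007061 to 103096002), rose from 32.6% to 66.4% (33.9 ± 8.39, SD, 6 pairs, adjusted p = 0.00259). Oxtr, the oxytocin receptor (chromosome 6, 112473683 to 112491035), rose from 17.9% to 32.3% (14.3 ± 7.29, adjusted p = 0.0203), and Ptgfr, the prostaglandin F receptor, by 9.70 points. Kcnma1 and Kcnn3, calcium-activated potassium channels of smooth muscle, rose by 22.0 and 22.9 points. Mylk, the myosin light-chain kinase, rose by 15.0 points and Adra1a, an alpha-adrenergic receptor, by 17.9 points. At equal covered length Slco2a1 (adjusted p = 0.0304) and Kcnma1 passed and the other 5 did not, among them Oxtr at 9.70 (adjusted p = 0.157) and Kcnn3 at 5.91. With the window at the gene end Oxtr (27.6, adjusted p = 0.0311) and Kcnn3 passed, while Slco2a1 came to 0.846 (adjusted p = 0.892), Ptgfr to 1.75 and Mylk to 0.0917, so none of the 7 passed under both. Adjusted p values for single genes here and below come from limma on the 6 paired differences.

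**Figure D2:**
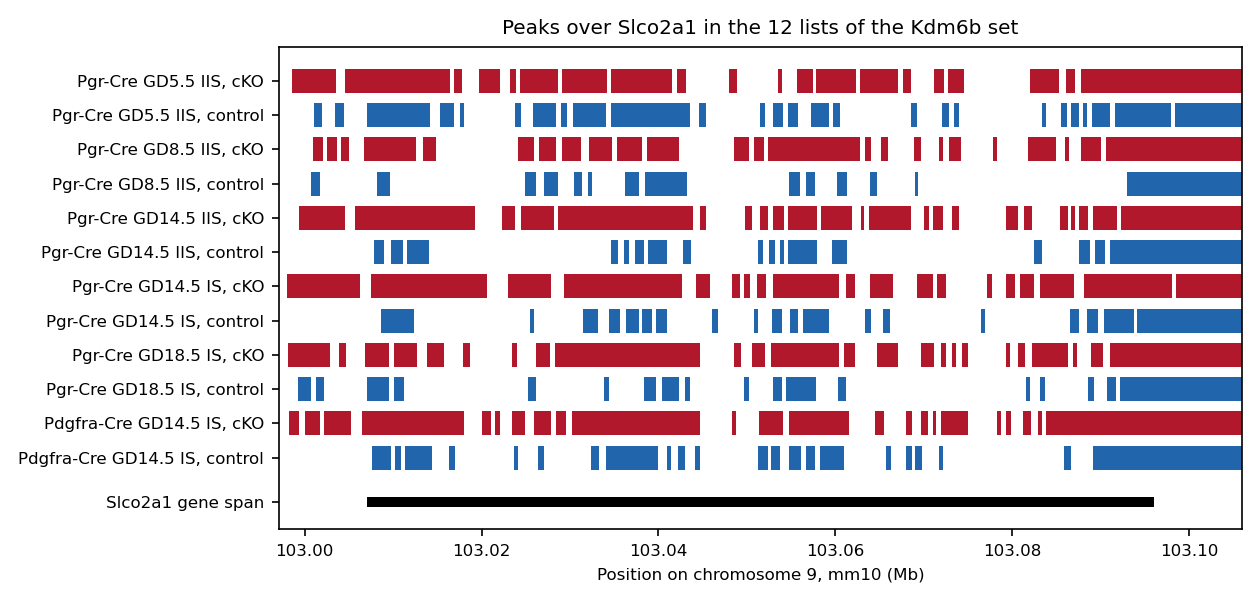
Peaks over Slco2a1 and 10 kb on either side (horizontal axis, position on chromosome 9 of mm10 in Mb) in the 12 lists of the Kdm6b set, 1 line per list, cKO in red and control in blue. Mean coverage of the gene was 66.4% in cKO lists and 32.6% in control lists.

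Of the 24 tested members of the contraction and parturition list, these 7 rose, 0 fell and 17 did not pass. Adjusted over the list alone, 9 rose and 1 fell. Oxtr, Ptgfr, Mylk and Adra1a lie outside the naming rule and were chosen after their values were seen. The mean of all 38 members was 32.3% in cKO and 27.7% in control, a difference of 4.57 ± 1.14 that was positive in 6 of 6 pairs (exact sign-flip permutation p = 0.03125, adjusted p over 18 lists = 0.1125). The median over members was 1.04, so the rise sits in part of the list.

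Of 18 tested decidual genes 3 rose, 0 fell and 15 did not pass, beside 853 risen of all 9843 tested genes, and 3 rose and 0 fell adjusted over the list alone. Cyp11a1, the cholesterol side-chain cleavage enzyme that starts steroid synthesis, rose by 10.9 points. Bmper, a BMP-binding protein, rose by 12.4 and Inhba, an activin subunit, by 11.5, and at equal covered length none of these 3 passed, at 9.97 (Cyp11a1), 6.98 (Bmper) and 17.9 (Inhba, adjusted p = 0.0510). With the gene-end window Inhba came to 1.74 and Bmper to 4.73. Among Wnt, BMP, FGF and hedgehog genes, 3 of 41 tested members rose and 0 fell, with 2 and 0 adjusted over the list alone. The Wnt ligand gene Wnt2 rose from 52.8% to 70.1%, but its difference was 2.67 at equal covered length and -1.44 with the gene-end window, neither past the threshold. The Wnt antagonist gene Dkk2 rose by 16.6 points and Wnt7a, chosen after its values were seen, by 6.49, and at equal covered length Dkk2 passed (11.3) and Wnt7a did not (adjusted p = 0.117). In the matrix list 3 of 14 tested members rose and 0 fell, and 4 rose and 1 fell adjusted over the list alone. Its largest rise was in Col8a1, a network-forming collagen chain, from 24.2% to 57.2% (33.0 ± 9.24, adjusted p = 0.00369). Timp3, an inhibitor of matrix metalloproteinases, rose by 12.3 points and Col9a1, chosen after its values were seen, by 7.08. Col8a1 passed at equal covered length (25.9), Col9a1 did not (1.19, adjusted p = 0.783), and Timp3 did not with the gene-end window (adjusted p = 0.284).

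Chemokine and inflammatory genes had the largest mean difference, 4.94 ± 3.34 over 42 genes, yet 0 of 29 tested members passed, and 0 adjusted over the list alone. Ccl8 and Ccl7, monocyte-attracting chemokines, had differences of 25.3 (adjusted p = 0.113) and 20.3 (adjusted p = 0.134). The means of the decidual (3.41 ± 1.67), Wnt and BMP (2.33 ± 1.06), matrix (1.51 ± 1.08) and chemokine lists were each positive in 6 of 6 pairs, with an exact sign-flip permutation p of 0.03125 and an adjusted p of 0.1125 over the 18 lists, so none passed after adjustment. The rotation test of limma (fry), which asks whether the tested members move on balance in 1 direction and was added after the data were seen, gave adjusted p = 0.00377 for contraction, 0.00965 for decidual and for Wnt and BMP genes, 0.0295 for matrix and for chemokines, and 0.0331 for endothelial genes. With the median difference of each pair subtracted, matrix genes no longer passed (adjusted p = 0.0723), while imprinted genes (0.0223, upward) and broadly active genes (0.0138, downward) did.

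In the Hox clusters, Hoxc8 fell by 14.7 points and Hoxc6 and Hoxc11 had differences of 16.7 and 15.1. None of the 3 passed at equal covered length, with differences of -15.2, -10.6 and -0.47, or with the gene-end window. Counted as deposited, 2 of 29 tested Hox genes rose and 1 fell, as did 2 and 1 adjusted over the list alone. Cdx1, a caudal homeobox gene, rose by 24.8 points and was 1 of 2 risen among 69 tested developmental transcription factors. The other was Pax8, chosen after its values were seen, at 9.40 points, which came to 2.65 at equal covered length (adjusted p = 0.642), and 0 passed adjusted over the list alone. Cdx1 passed at equal covered length (31.4) and not with the gene-end window (adjusted p = 0.708). Casq2, the calsequestrin of cardiac and smooth muscle calcium stores, rose by 24.6 points (13.5 at equal covered length, and not past the threshold with the gene-end window), with 1 of 7 tested smooth muscle genes risen, and 2 risen and 1 fallen adjusted over the list alone. Cdh1, which encodes E-cadherin, rose from 77.3% to 87.8% and was the 1 of 14 tested epithelial markers to pass, but not at equal covered length (11.7, adjusted p = 0.0589). Tek, the angiopoietin receptor, rose from 1.26% to 10.1% and was the 1 of 13 tested endothelial markers to pass, but not with the gene-end window (34.8, adjusted p = 0.0731). The imprinted genes Kcnq1 and Mest rose by 8.90 and 8.57 points, 2 of 11 tested, with 4 risen and 2 fallen adjusted over the list alone, and neither passed at equal covered length (2.96, adjusted p = 0.287, and 6.38, adjusted p = 0.298).

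Rbbp7 was the 1 of 7 tested Polycomb and demethylase genes to change, downward, and it passed adjusted over the list alone. The mean of the steroid receptor and progesterone-responsive list differed by -0.73 ± 1.57 (exact sign-flip permutation p = 0.344, positive in 3 of 6 pairs), with 0 risen and 1 fallen of 16 tested members, and 0 and 0 adjusted over the list alone. Among markers of other cell types that a fibroblast preparation could hold, 0 of 15 tested immune and 0 of 4 tested trophoblast markers passed. The smooth muscle, epithelial and endothelial lists had 1 call each, of 7, 14 and 13 tested. Over all 9843 tested genes 853 rose and 831 fell, so lists this short hold few calls in any case. These counts do not tell whether the make-up of the preparation differed. Fibroblast identity genes averaged 5.62% in cKO and 4.79% in control, broadly active genes 4.23% and 5.13%, and 0 of 5 tested genes passed in each list. None of 4 tested cell cycle inhibitor and senescence genes passed. The Kdm6b gene itself lay at 0 to 7.1% in the 16 lists and Pgr at 0 in all 16, so neither reports on the deletion. Pdgfra averaged 23.4% in cKO and 22.9% in control.

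**Figure D3:**
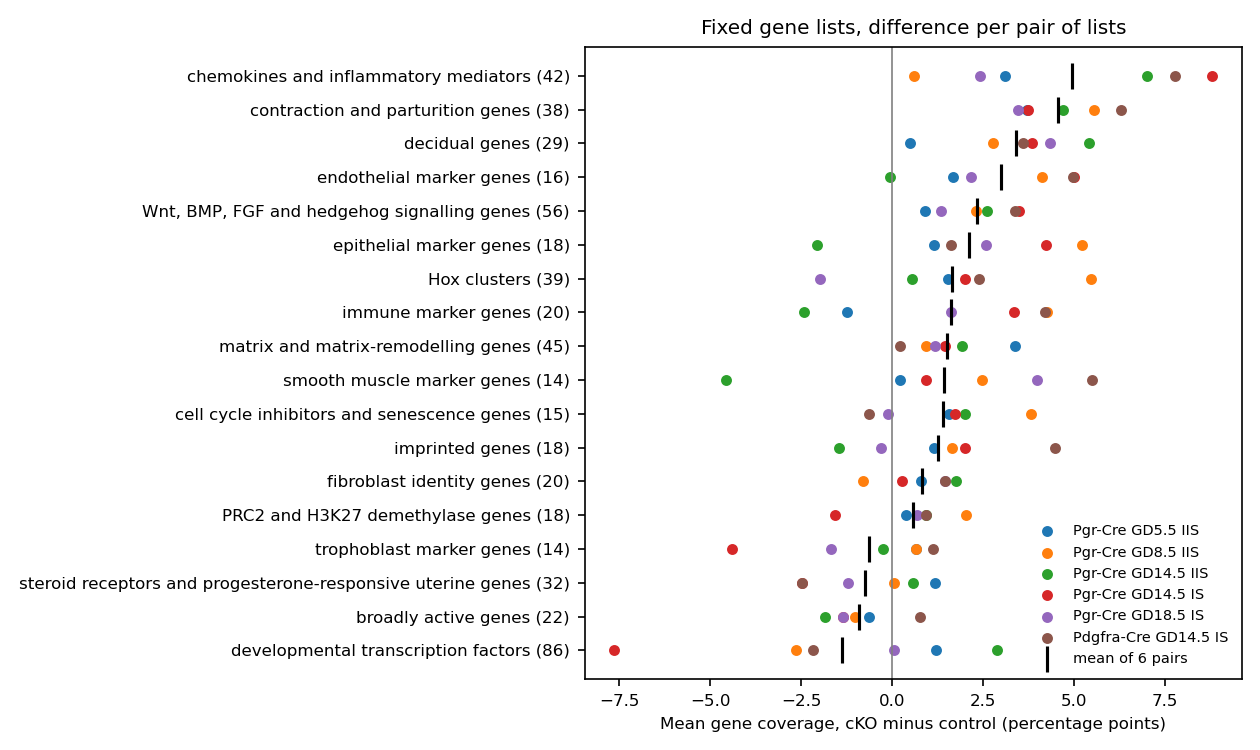
Mean gene coverage of 18 fixed gene lists, cKO minus control in percentage points (horizontal axis), with 1 point per pair of pooled lists and a black bar for the mean of 6 pairs. Numbers in parentheses are genes per list. The contraction, decidual, chemokine, matrix and Wnt lists lie above 0 in 6 of 6 pairs.

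Over all 9843 genes tested with limma, 853 rose in cKO by a median of 14.3 points and 831 fell, with a median difference of -22.3. Genes that rose had a median control coverage of 24.4% and genes that fell one of 56.9%. Of the genes that rose, 794 did so in all 6 pairs, and of those that fell, 711. With each pair left out in turn, which leaves fewer pairs to test, 456 to 582 genes rose and 346 to 814 fell. By the naming rule the strongest rises were in Slc14a2, a urea transporter (15.6% to 57.2%, adjusted p = 0.000772), Hsd11b1, which regenerates active glucocorticoid (13.6% to 49.7%, adjusted p = 0.000826), and Icos, a T-cell costimulatory receptor (22.6% to 58.8%). Adtrp, Mrln, the muscle micropeptide myoregulin, Cd101, a leukocyte surface protein, and Slc13a4, a sulfate transporter, rose by 48.1, 51.4, 48.8 and 39.0 points. Reg4, Wwox and Zfp366 rose by 25.8, 30.6 and 25.6 points. Hsd11b1, Adtrp, Mrln, Wwox and Slc13a4 passed both at equal covered length and with the gene-end window. Reg4 did not pass at equal covered length (29.6, adjusted p = 0.0659), and with the gene-end window Slc14a2 came to 7.88 (adjusted p = 0.620) while Icos (60.6, adjusted p = 0.0509), Cd101 (40.9, adjusted p = 0.0507) and Zfp366 (adjusted p = 0.0674) missed the threshold.

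The strongest falls were in H2-M1, a non-classical MHC class I gene (67.3% to 6.86%, adjusted p = 0.00217), the X-linked Samt2b (78.2% to 23.1%, adjusted p = 0.00163) and Eola1 (55.1% to 19.5%), the olfactory receptor genes Olfr873, Olfr525 and Olfr18 (differences of -48.1, -38.6 and -24.8), the vomeronasal receptor gene Vmn2r80 (-36.7), the cytochrome P450 gene Cyp2c55 (-30.2), the epididymal secretory protein gene Crisp4 (-25.7) and Gm4802 (-42.1). At equal covered length Vmn2r80 was the 1 of these 10 to pass, Olfr18 had too little coverage to be tested, and H2-M1 came to -24.5, Samt2b to -18.2, Eola1 to -14.2 and Olfr525 to -13.7, while Crisp4 kept its size (-27.3). With the gene-end window Vmn2r80 (-21.7, adjusted p = 0.247), Cyp2c55 and Crisp4 did not pass and the other 7 did, so none of these 10 passed under both. Next, 16 autosomal gene families picked after the data were seen were compared. The 1104 olfactory receptor genes averaged 21.1% in cKO and 29.8% in control (-8.76 ± 4.63, lower in 6 of 6 pairs), and of 548 tested, 125 fell and 6 rose. Vmn1r, Vmn2r and Klr genes differed by -5.74, -4.39 and -6.95, each lower in 6 of 6 pairs. For each of these 4 families the exact sign-flip permutation p was 0.03125 and the adjusted p over 16 families 0.125. Cyp and Defb genes, which are not receptors, differed by -5.78 and -5.34, each lower in 5 of 6 pairs (exact sign-flip permutation p = 0.0625, adjusted p = 0.125). The Pgr-Cre control list of GD14.5 IS exceeded the Pdgfra-Cre control list by 7.95 points for olfactory receptor genes and by 5.08 for Klr genes, a difference between controls of similar size, and by 3.14 and 0.542 at equal covered length.

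The genes that rose or fell lie mostly outside the strongest peaks, since 1531 of these 1684 genes had no peak with a -log10 q of at least 2 in any of the 12 lists. With such peaks alone limma called 0 genes up and 5 down of 972 tested (171 at an unadjusted p under 0.05). Of the 25 first calls still tested there, 15 had the opposite sign and 0 passed, and the contraction, decidual, chemokine, matrix and Wnt list means turned to between -1.90 and -8.43. At equal covered length 282 genes rose and 429 fell, including 246 and 258 of the original calls, and the list means came to 2.53 (contraction), 2.72 (decidual), 3.41 (chemokine), 0.821 (Wnt) and -0.26 (matrix). With the window at the gene end 130 genes rose and 121 fell, including 88 and 104 of the original calls. Of the 1456 original calls still tested with that window, 104 had the opposite sign.

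Pair by pair, genes were counted as gained or lost when their coverage differed by at least 50 points between 2 lists. Genes said below to have gained or lost passed that size in the lists as deposited and at equal covered length. The exceptions are Lmod1 and Ccl11 in the B6CBAF1/J set. Members of the fixed lists are instead given with their differences, most of them below that size, and a list called higher or lower is so in its mean alone. Holding at equal covered length was part of the naming rule, so it is no separate support. Of all 253 changes picked by that rule, 3 kept 50 points with peaks at a -log10 q of at least 2. Of the others, 248 fell short of that size and 2 turned. With 5 kb flanks 142 kept 50 points and 111 did not. No test can be made within a pair, and the background is the pair of control lists of GD14.5 IS, where 65 genes were higher and 9 lower in the Pgr-Cre control list than in the Pdgfra-Cre control list (87.8% of changed genes, exact 95% interval 78.2 to 94.3), 81 and 79 at equal covered length, and 6 and 307 with peaks at a -log10 q of at least 2, which turns the direction. In that background Sprr2i, a cornified-envelope gene, and olfactory receptor genes such as Olfr61 (86.3% against 0%) were higher, and the homeobox and forkhead genes Barhl2, Irx5 and Foxl2 lower. Across genes, the cKO differences of any 2 pairs correlated with Pearson's r of 0.285 to 0.591 (median 0.475 over 15 combinations), where genes are not independent replicates.

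On GD5.5, cKO fibroblasts between implantation sites gained H3K27me3 over Cpa1, a pancreatic carboxypeptidase (93.6% against 5.18%), Cd93, a receptor of endothelial and myeloid cells (92.8% against 6.14%), Mt1, a metallothionein (100% against 38.2%), Ctrb1, Tnp1 and the taste receptor gene Tas2r119. They lost it over the tight-junction gene Cldn17 (10.7% against 85.5%), the X-linked homeobox gene Rhox9 (11.2% against 77.0%), Prss37 and 7 olfactory receptor genes, among them Olfr651 (14.4% against 91.0%). For contraction genes the mean was 3.72 points higher, with Gjb2, a gap junction protein, at 28.6 and Kcnma1 at 21.4, and that of the matrix list 3.38 higher (2.03 at equal covered length), with Timp1 at 36.6 (59.6 at equal covered length) and Tnc, tenascin C, at 34.6. In all 19 genes gained and 51 lost coverage (27.1% gained, exact 95% interval 17.2 to 39.1), but 205 and 184 with the gene-end window (52.7%), so this direction turned. These 70 genes are fewer than the 74 of the background, against 202 and 160 at equal covered length. By GD8.5 the cKO gained Cd93 (95.9% against 0%), Cpa1, Tas2r119, the collagenase gene Mmp1a (76.3% against 5.90%), Cd101, Xcl1, a lymphocyte chemokine, and Mrln, and lost H2-M1, the kallikrein gene Klk1b26 and olfactory receptor genes such as Olfr64 (0% against 91.1%). For contraction genes the mean was 5.53 points higher (1.75 at equal covered length), with Kcnma1 at 24.4 and, in the other direction, Gja1 at -29.9. Cell cycle inhibitors had a mean 3.83 higher, with a median over 15 members of 0, 0 gained and Cdkn1a at 27.4. On that day 37 genes gained and 137 lost coverage (21.3% gained, 15.4 to 28.1), 1 and 331 at a -log10 q of at least 2, and 276 and 317 with the gene-end window (46.5%).

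On GD14.5 between implantation sites, the mean of the chemokine list was 7.00 points higher in cKO, with a median over members of 0 and 0 of 42 members gained. Its largest differences were in Vcam1, a leukocyte adhesion molecule, at 49.1, Cxcl10, an interferon-induced chemokine, at 45.7, Ccl7 at 39.7 and Il6 at 32.4, and the last 3 came to 15.2, 22.1 and -7.92 at equal covered length. The decidual list had a mean 5.41 higher (median 2.72, 0 of 29 gained) with the stromal transcription factor gene Hand2 at 22.3 and Inhbb at 20.9, which came to 51.1 and 0 at equal covered length. Developmental transcription factors had a mean 2.89 points higher, with a median over 86 members of 0, 0 gained and Cdx1 at 43.2. Tgfbi, an adhesion protein of the matrix (75.0% against 8.82%), Bbox1, which makes carnitine (70.3% against 10.6%), Xcl1, the potassium channel gene Kcng4, S100a14 and Dbpht2 gained. Ly6f (5.08% against 92.4%), the antimicrobial lectin gene Reg3g (9.61% against 93.5%), Cyp2d40, Spinkl, Vmn1r10 and 5 olfactory receptor genes lost. In all 23 genes gained and 236 lost coverage (8.88% gained, 5.71 to 13.0), at equal covered length 90 and 269 (25.1%), and with the gene-end window 291 and 465 (38.5%). With peaks at a -log10 q of at least 2 it was 83 and 17 (83%), so this direction turned.

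At GD14.5 implantation sites of Pgr-Cre cKO the monocyte and eosinophil chemokines Ccl8, Ccl11 and Ccl7, neighbours on chromosome 11, were 62.2, 57.2 and 54.0 points higher, within a chemokine list whose mean was 8.79 higher (median 1.37), though Ccl8 came to 0 at equal covered length. Bbox1 (73.5% against 6.03%), Fam170b (86.2% against 14.6%), Fibin, Cpa1, the lactate receptor gene Hcar1, the nucleotide receptor gene P2ry6 and the lens gene Cryge gained. The X-linked genes Gm732 (0% against 100%), Cylc1, Cetn2, a centrin, and Tmem185a lost, as did Vmn1r180 and 5 olfactory receptor genes. The mean of the developmental transcription factors, higher in the IIS pair of that day, was 7.63 points lower (-17.7 at equal covered length), with a median of -3.30 and 1 of 86 lost, led by Cdx2 at -59.5 and Foxd3 at -44.7, beside a difference of -6.32 between the 2 control lists of that stage (-10.7 at equal covered length). In all 48 genes gained and 208 lost coverage (18.8% gained, 14.2 to 24.1), of which 103 losses were X-linked, 0 and 349 at a -log10 q of at least 2, and 324 and 382 with the gene-end window (45.9%).

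In the Pdgfra-Cre pair of the same stage, Cpa1 (89.2% against 18.2%), Mrln (73.8% against 14.1%), Hcar1 (63.7% against 8.98%), Cryge, Xcl1, Pabpc2, Naa11 and Vmn1r223 gained. The X-linked genes Mycs, Samt2b and Ube2dnl1 lost, with 4 olfactory receptor genes, Vmn1r188 and Ccnb1ip1, a meiotic crossover gene. Chemokines had a mean 7.78 points higher (1.49 at equal covered length) with Cxcl15 at 38.2 and Ccl8 at 36.9, which came to -19.4 and 12.7 there. That of the contraction list was 6.28 higher (2.71 at equal covered length) with Mylk at 28.7 and Ptgfr at 20.1 (7.28 there), and that of the progesterone-responsive list 2.48 points lower (-5.08 at equal covered length), led by the activin antagonist gene Fst at -41.5. Here 49 genes gained and 31 lost (61.3% gained, 49.7 to 71.9). But at equal covered length 48 gained and 208 lost (18.8%) and at a -log10 q of at least 2 it was 0 and 524, so the direction of this share turned. These 80 changed genes stand beside 74 in the background, which uses the same Pdgfra-Cre control list (256 and 160 at equal covered length). Against that list the Pgr-Cre control also had 6 genes higher and 307 lower at a -log10 q of at least 2. A loss of that kind is thus not particular to cKO lists.

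At term, on GD18.5, cKO fibroblasts of the implantation site gained Bbox1 (67.3% against 0.889%), Myf6, a muscle regulatory factor (95.8% against 31.9%), Sod3, the extracellular superoxide dismutase (60.4% against 8.19%), Rnase1, Defb28 and Fam170b. They lost Ly6f (0.928% against 93.6%), the MHC class I genes H2-M1 (10.2% against 94.5%) and H2-M11 (0% against 85.8%), Hsfy2, the X-linked histone gene H2al3, Vmn1r10, Vmn1r222 and 3 olfactory receptor genes. Decidual genes had a mean 4.33 points higher (median 0), with Il11, a cytokine of decidualization, at 36.6, Inhba at 25.6 and Bmper at 24.8 (15.8 at equal covered length). The contraction mean was 3.46 higher (0.421 at equal covered length, median 0), with Slco2a1 at 36.4, Kcnn3 at 24.2 and Kcnma1 at 19.7, the last 2 at 7.31 and 9.95 there. In all 20 genes gained and 157 lost (11.3% gained, 7.04 to 16.9), 6 and 141 at a -log10 q of at least 2, and 192 and 369 with the gene-end window (34.2%).

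**Figure D4:**
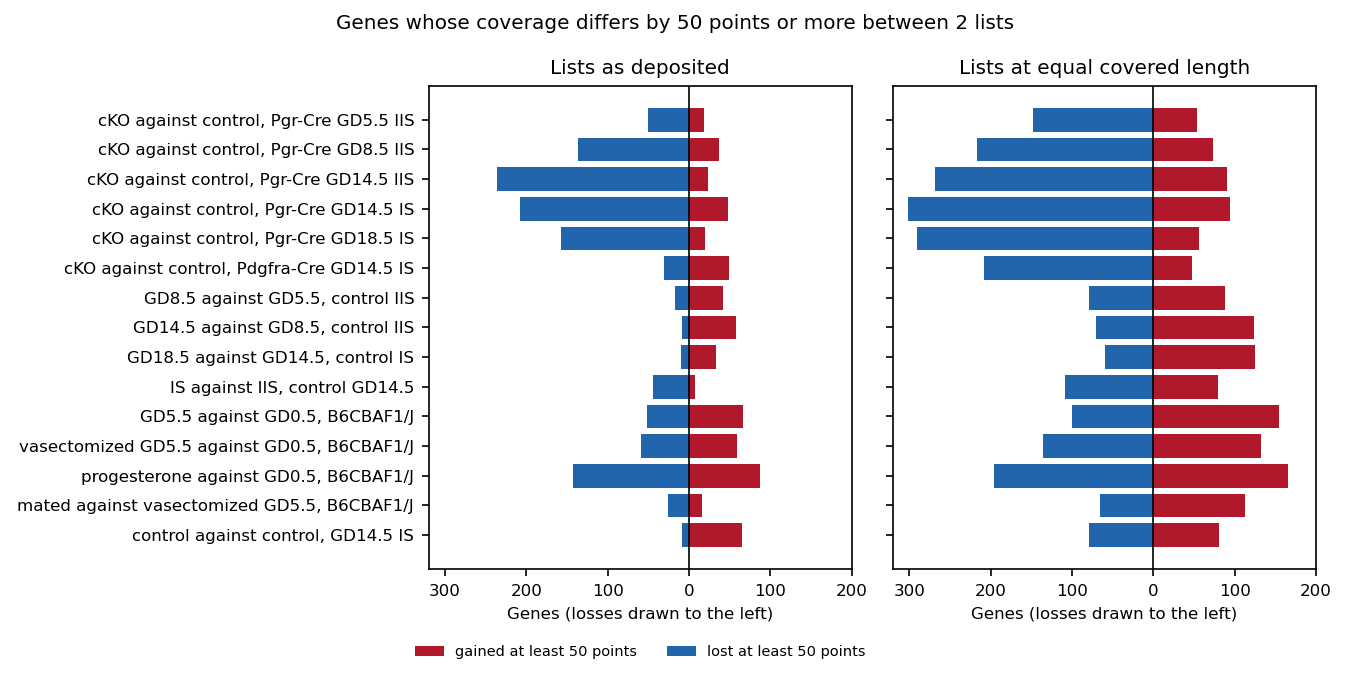
Number of genes (horizontal axis) whose coverage differed by at least 50 percentage points in 14 comparisons and in the control against control background, gains to the right and losses to the left, for lists as deposited and at equal covered length. Losses exceed gains in all 5 Pgr-Cre cKO comparisons in both panels, and in the Pdgfra-Cre comparison only at equal length.

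The control lists were next compared along pregnancy, the course that the title of the series sets against gestation length. Between GD5.5 and GD8.5, the mean of the decidual list differed by -5.03 points between implantation sites, with 0 of 29 members past the size rule and a median of -0.887, and with Inhbb at -27.5, Bmp2, a decidual morphogen, at -19.2 and Il11 at -18.1, and the means of the Wnt and BMP list and of the cell cycle inhibitors differed by -3.91 and -4.06 (Cdkn1a at -44.7). Tgfbi (26.5% against 89.2%), the calcium-binding protein gene S100g, Sox8, S100a16 and Ly6g6c lost, and Fshb, a pituitary hormone subunit (94.8% against 21.5%), Krtap19-3, Tas2r140 and 5 olfactory receptor genes gained. In all 42 genes gained and 17 lost (71.2% gained, 57.9 to 82.2), but 120 and 204 with the gene-end window, so this direction turned. From GD8.5 to GD14.5 the means of the chemokine (-2.53), contraction (-2.10) and decidual (-1.32) lists were lower (-3.91, -4.74 and -4.73 at equal covered length), with Vcam1 at -48.5, the connexin gene Gja1 at -37.5, Ptgs2, the inducible prostaglandin synthase, at -34.4 and Inhbb at -41.6. Penk, the enkephalin precursor (21.5% against 100%), and the metallothionein gene Mt2 lost, while Ly6g6d, Ly6g6e, the epidermal protease gene Asprv1, Myog, Lcn2, which encodes lipocalin (99.5% against 44.5%), and the mast cell protease gene Mcpt8 gained. In all 58 genes gained and 9 lost (86.6% gained, 76.0 to 93.7), but 2 and 344 at a -log10 q of at least 2, so this direction turned.

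From GD14.5 to GD18.5 at implantation sites, the mean of the decidual list differed by -3.86 (median 0), led by Il11 at -41.7 and Tdo2, the tryptophan dioxygenase of decidua, at -19.7 (-5.15 at equal covered length), and that of the developmental transcription factors was 3.54 points higher (median 0). Irx5 (100% against 46.5%), Gpihbp1, which anchors lipoprotein lipase, Defb4 and Krt34 gained, and Taar7a, Tas2r140 and Olfr1032 lost, within 33 genes gained and 10 lost (76.7% gained, 61.4 to 88.2), but 8 and 163 at a -log10 q of at least 2, so this direction turned. Between sites on GD14.5, Dbpht2 (85.1% against 12.9%) was higher at the implantation site, and Mcpt8, Fut4, Barhl2, Spink11 and Vmn1r33 lower, within 7 genes gained and 44 lost (13.7% gained, 5.70 to 26.3), 79 and 109 at equal covered length, and 130 and 149 with the gene-end window. With peaks at a -log10 q of at least 2 it was 217 and 4 (98.2%), so this direction turned too. The lists behind the GD14.5 IS values of Pgr-Cre fibroblasts carry the name of a separate round of peak calling. The 4 steps changed 43 to 67 genes beside 74 in the background, and at equal covered length 167 to 194 beside 160. Across genes the change seen in controls and the change seen in cKO correlated with r of 0.234 from GD5.5 to GD8.5, 0.110 from GD8.5 to GD14.5 and 0.0167 from GD14.5 to GD18.5.

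In B6CBAF1/J females natural mating, mating without embryos and progesterone were each set against GD0.5. The progesterone females were non-pregnant and have no gestation day, so that comparison also carries the difference in mating. The natural mating list is IIS tissue and the GD0.5 list uterus, so site and time cannot be told apart there. The 3 comparisons share the GD0.5 list as their control, so they are not independent. The smooth muscle genes Acta2 and Lmod1 gained H3K27me3 in all 3 and carry the mean of their list, which was 13.0 points higher after natural mating, 13.0 after vasectomized mating and 12.7 with progesterone. These were the 2 of 14 members gained each time, and the medians over members were 5.07, 1.99 and 0.579. Acta2, smooth muscle actin, was 55.5, 63.4 and 63.1 points higher and Lmod1, a leiomodin of the same cells, 52.9, 52.0 and 63.6, which after natural mating came to 45.9 at equal covered length. Several members, Acta2 among them, also stand in the contraction list. Pla2g3, a secreted phospholipase (86.4%, 87.9% and 89.3%, against 0% on GD0.5), the insulin-regulated glucose transporter gene Slc2a4 and Inpp5j gained in all 3. The quinone reductase gene Nqo1 (73.8%, 68.3% and 80.1%, against 0%) and Sectm1b (84.7%, 71.8% and 86.8%, against 7.39%) were likewise higher in all 3. Inhbb, the activin B subunit, gained after natural mating (84.6% against 0%) and after vasectomized mating (78.9% against 0%).

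Among the genes lost in this set, most of the largest with progesterone were olfactory receptor genes, such as Olfr65 (0% against 100%). Ccl11, the eosinophil attractant eotaxin, stood at 13.4% after natural mating, 0% after vasectomized mating and 0% with progesterone, against 80% on GD0.5 (differences of -38.2, -51.7 and -51.7 at equal covered length), and Foxl2, a forkhead factor of ovary and uterus, at 58.9%, 19.7% and 0% against 82.0%. Gm32280 stood at 0% in all 3 against 85.9%. The mean of the chemokine list differed by 1.88 after natural mating, inside the range of random lists, by -2.67 after vasectomized mating and by -3.38 with progesterone (-2.93, -5.26 and -4.90 at equal covered length, 2.38 in each at a -log10 q of at least 2), with 1 of 42 members lost in each. Ccl12 (9.54% against 74.2%) and C5ar1, the complement anaphylatoxin receptor (4.78% against 66.8%), lost after vasectomized mating. Developmental transcription factors had means that differed by -3.74 after vasectomized mating (-6.01 at equal covered length) and by -7.95 with progesterone, with Cdx1 at -53.5, Sox2 at -44.8 (-69.3 at equal covered length) and Nkx6-1 at -43.8. Natural mating gave 66 genes gained and 52 lost (55.9% gained, 46.5 to 65.1), vasectomized mating 59 and 59 (50%, 40.7 to 59.3) and progesterone 87 and 143 (37.8%, 31.5 to 44.4). With peaks at a -log10 q of at least 2 progesterone gave 229 and 40 (85.1%), so this direction turned. Across genes the natural, vasectomized and progesterone lists correlated at r of 0.977 to 0.980 with each other and at 0.947 to 0.963 with GD0.5.

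Natural mating was also set against vasectomized mating on GD5.5, a comparison in which both the embryos and the tissue differ. Foxc2, a forkhead factor (90.7% against 25.2%), Bhlhe41, a circadian repressor, Nr2e3 and Tmem190 were higher after natural mating, and the X-linked Tex13c3 and H2ab3, Vmn1r42 and Gtsf1l lower. Chemokines had a mean 4.54 points higher (2.33 at equal covered length, median 0), with Cxcl10 at 48.6, Lif, the implantation cytokine, at 47.3, Cxcl14 at 29.6 and Ccl8 at 25.2, the last 2 at 0 there. That of the Wnt and BMP list was 3.46 points higher, with Nog, a BMP antagonist, at 47.2. In all 16 genes gained and 26 lost (38.1% gained, 23.6 to 54.4), but 113 and 66 at equal covered length (63.1%), 151 and 118 with the gene-end window (56.1%) and 91 and 32 at a -log10 q of at least 2, so this direction turned. The mated sample is IIS tissue and the vasectomized sample whole uterus.

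List means given for single comparisons are those outside the middle 95% of 10000 random lists matched on mean coverage, with the contraction list of the Pdgfra-Cre pair (percentile 96.0), the chemokine list after natural mating (percentile 65.8) and values at other settings as exceptions. Of 252 such means 50 lay outside (19.8%), beside 3 of 18 in the background between controls (16.7%), so a place outside these limits does not set a comparison apart from the background. In 32 of the 50 the median over members was 0, and in 38 no member differed by 50 points. Of these 50 the sign was the same at equal covered length in 47, and at a -log10 q of at least 2 it was the same in 18, opposite in 21 and 0 in 11.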

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

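The explanations weighed here were chosen after the results were seen, and the test of enrichment for the genes was the only one of these whose prediction was written before its value was computed.

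The lower H3K27me3 coverage of the X in cKO lists was weighed first. A difference in total covered length does not account for it, since the mean log2 ratio at equal covered length was -0.6524 (exact sign-flip permutation p = 0.03125, lower in 6 of 6 pairs). Peaks on Y outside its last Mb covered at most 0.633 kb in any cKO list, so they give no sign of male cells in the cKO samples. No list of male cells shows how much Y such cells would place inside peaks, so male cells are not excluded. A difference in enrichment between libraries remains open, because over the 6 control lists X length and log2 length at -log10 q of at least 2 had r = 0.05514 (exact permutation p = 0.9097). The X signal lies almost wholly in weak peaks, with at most 0.0605 Mb of X at that threshold in any of the 12 lists. Whether X inactivation was altered was not tested.

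The genes that rose and fell over the 6 pairs were weighed next. Chance assignment of sign does not readily account for them, since 1 of 32 sign flips, the real one, gave as many as 1684 genes. The highest other gave 0. A share of 1 of 32 is the smallest this test can give, and it cannot tell a biological from a technical difference shared by the pairs. Of the 746 risen and 710 fallen genes still tested at equal covered length, 246 and 258 passed again. The other calls ended as the differences shrank and their spread grew. For the 500 risen genes concerned the median difference went from 13 to 7.998 points and the median SD over pairs from 6.403 to 8.933, and for the 452 fallen genes from -24.65 to -17 and from 13.11 to 17.87. A difference in total covered length does not account for the whole of either direction, since over all genes still tested the median difference averaged 10.21 ± 1.258 points (SD, 6 pairs) for those that rose, against 14.39 as deposited, and -17.26 ± 2.337 for those that fell, against -20.25, with the same sign in 6 of 6 pairs. A difference in enrichment remains open, with r = 0.3976 over the 6 control lists (exact permutation p = 0.4264). GD14.5 IIS was the 1 pair in which cKO held more length at -log10 q of at least 2. It showed the sign found in the other 5 pairs in 88.6% of genes that rose there and 96.2% of genes that fell. Of all tested genes 38.1% were higher in cKO in that pair. For the Pdgfra-Cre pair the shares were 96.4% and 71.4%, with 63.2% of all tested genes higher. Because no link between that length and these genes was found among controls, this single pair does not decide on enrichment.

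The lower coverage of olfactory and vomeronasal receptor genes was weighed last. At equal covered length the olfactory receptor mean was -7.094 points, so total length does not account for it. A difference in enrichment remains open, with r = -0.7034 over the 6 control lists (exact permutation p = 0.1347). The 2 control lists of GD14.5 IS differ by 3.14 points for the same genes at equal covered length, and by 7.946 as deposited where the cKO value was -8.755. No biological explanation was tested.

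Covered length at a fold of at least 3 in the Pdgfra-Cre GD14.5 IS pair stood far from the other 5 pairs, with a log2 ratio of -0.7935 (gap over range 0.691), the 1 such pair among 25 groups examined, where chance gives about 1 in 20. For steroid receptors and progesterone-responsive genes, all pairs between implantation sites and all pairs at implantation sites had cKO differences of opposite sign, with means -2.653 points apart in the second minus the first. The split rests on the GD8.5 pair at 0.04371, which came to -1.126 at equal covered length and so broke the pattern, and this difference between groups was not tested. Data outside the comparisons also held a signal, since all 16 lists had peaks in the last Mb of chromosome Y, between 90720796 and 90813832, covering 17.6 to 27.9 kb per list with folds of up to 5.42.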

How the results depend on the processing

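The gene-end window, autosomes alone, limma with a trend, the rotation test and the alternatives for the X and for olfactory receptor genes were chosen after seeing the data. No paired analysis was possible because each group has 1 pooled list, as far as single samples go, while the pairs of lists were tested as pairs and an unpaired fit gave 682 risen and 784 fallen. The X was lower in all 6 pairs as deposited, at equal covered length and as a share of covered length. It was also lower in all 6 at -log10 q of at least 2, where it held at most 0.0605 Mb in any list. Total covered length was lower there too in 5 of 6 pairs, so that setting does not single out the X. With peaks at a fold of at least 3 the X was instead higher in cKO in all 6 pairs. It held at most 0.00732 Mb in any list at that fold. With each pair left out, the X log2 ratio ranged from -0.3936 to -0.269, the olfactory receptor mean from -10.31 to -7.765, total covered length from 0.02484 to 0.09651, genes risen from 456 to 582, genes fallen from 346 to 814, and the trophoblast mean from -0.9994 to 0.1004. The first 2 lost p under 0.05 there because 5 pairs cannot go below 0.0625. At -log10 q of at least 2, total covered length came to -1.912, genes risen to 0 and fallen to 5, the olfactory receptor mean to -0.228, and list means to -0.5836 (Polycomb), -1.427 (Hox), -5.203 (decidual), -1.964 (contraction), -1.902 (chemokines), -2.039 (matrix), -8.427 (Wnt), -5.672 (epithelial), -4.989 (endothelial), -0.8333 (immune) and -2.414 (imprinted). Shares gained there were 15.18, 0.3012 and 83% for cKO at GD5.5, GD8.5 and GD14.5 IIS, 0 and 4.082% at GD14.5 and GD18.5 IS, 0% for Pdgfra-Cre, 97.48, 0.578, 4.678 and 98.19% for the 4 control steps, 85.13% for progesterone, 73.98% for mated against vasectomized and 1.917% for control against control. Mrln came to -0.4095 in the Pdgfra-Cre pair and Fut4 to 17.37 between sites. At a -log10 q of at least 2 few first calls could be tested again, since 25 of 1684 genes keep a mean coverage of 5%. Of these 25 genes 15 had the opposite sign. That does not account for the low counts among all 972 genes tested there, of which 171 had an unadjusted limma p under 0.05. For this and the other changes the cause was not tested. At a fold of at least 3 total covered length came to -0.08984. At equal covered length 282 genes rose and 429 fell, list means came to -1.01 (Polycomb), -5.079 (Hox), -0.2634 (matrix), -0.9652 (immune) and -0.1105 (imprinted), Hoxc11 to -0.4668 and Hoxc6 to -10.59, and shares gained to 25.07% (GD14.5 IIS), 18.75% (Pdgfra-Cre), 52.7, 63.92 and 42.02% (GD8.5, GD14.5 and site steps in controls), 45.71% (progesterone), 63.13% (mated against vasectomized) and 50.62% (control against control). With the gene-end window 130 genes rose and 121 fell, Wnt2 came to -1.442, and shares gained to 52.7, 46.54 and 38.49% at GD5.5, GD8.5 and GD14.5 IIS, 45.89 and 34.23% at GD14.5 and GD18.5 IS, 72.41% for Pdgfra-Cre, 37.04, 72.6, 60.98 and 46.59% for the 4 control steps, 49.34% for progesterone and 56.13% for mated against vasectomized. Among named genes tested over the 6 pairs at equal covered length, 17 kept their call, 26 lost it and 2 turned. Without the coverage filter 545 fell. With 5 kb flanks the share gained was 47.37% at GD5.5, 12.5% at GD14.5 IS, and 100% for GD18.5 against GD14.5 and for control against control, and at 25 points 40.37, 35.91 and 22.75% at GD5.5, GD8.5 and GD14.5 IIS, 35.06 and 25.1% at GD14.5 and GD18.5 IS, and 53.52 and 33.54% for the GD8.5 and site steps in controls. The cause was not tested. The rotation test gave adjusted p = 0.00377 (contraction), 0.00965 (decidual), 0.00965 (Wnt), 0.0295 (chemokines), 0.0295 (matrix) and 0.0331 (endothelial).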

Other observations

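The 2 hypotheses below were written before their tests, but related list values had been seen by then, namely lower contraction and chemokine lists on GD14.5 than on GD8.5 in controls and a higher contraction list with progesterone, and 6 changes were computed where 2 had been predicted.

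The first hypothesis was that genes with the largest cKO gain at implantation sites are genes that lose H3K27me3 in control fibroblasts as pregnancy advances between implantation sites. For the 500 genes with the largest gain, the mean control change from GD5.5 to GD14.5 was -4.045 points against 4.807 for matched random lists (percentile 0). This leaves the hypothesis open, because genes picked for a large gain in cKO are partly genes with low coverage in the GD14.5 and GD18.5 controls, which favours such a fall and which lists matched on mean coverage do not carry. From GD5.5 to GD8.5 the control change was -6.087 (percentile 0), and in cKO lists the change from GD5.5 to GD14.5 was -0.7191 (percentile 41.94). The genes were picked from the 3 implantation-site pairs, whose lists are not among those in the test but belong to the same set, and each change rests on 1 list per group.

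The second hypothesis was that the same genes gain H3K27me3 between GD0.5 and GD5.5 in B6CBAF1/J females, whose lists are separate from those used to pick the genes. Their mean change was 3.453 points after natural mating (percentile 100) and 1.522 with progesterone (percentile 99.97), but -1.354 after vasectomized mating (percentile 2.49). The vasectomized mating thus went against the direction of the other 2, and it differs from natural mating both in the absence of embryos and in the tissue sampled. These changes share the GD0.5 list and rest on a single list per group. The percentiles therefore cover the choice of genes only, not the spread between lists.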
